A study of Rattus norvegicus with 64 samples.

How the data were processed

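RNA sequencing measured gene expression in the hippocampus and the cortex of 32 rats, giving 64 libraries. The rats carried ApoE3 or ApoE4, human forms of the lipid carrier apolipoprotein E, and received doxorubicin, an anthracycline chemotherapy drug that acts on topoisomerase II, or phosphate-buffered saline (PBS). Each of the 8 groups of region, genotype and treatment held 8 libraries, from 4 males and 4 females. No library was left out. Rat numbers ran in unbroken blocks by genotype, sex and treatment. A batch that follows these blocks, which the labels do not give, could not be told apart from genotype, treatment or their differences by sex.

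Per the submitters' processing notes, the authors aligned the reads with STAR 2.5.2b and compared groups with DESeq2, whose version is not given. The read counter, the genome build and the strandedness of the libraries are not stated. The deposited count tables hold the unmodified count of reads per Ensembl rat gene, 1 table per region and genotype, each with 32644 rows: 32551 gene identifiers, 92 ERCC spike-in sequences and 1 row for an ApoE3 donor sequence. The authors' comparison tables give a log2 fold change of doxorubicin against PBS, a p-value and an adjusted p-value per gene. As deposited, these tables of the authors also hold a signal per gene and library, which equals the count divided by 1 size factor per library. The authors kept rows with a total of at least 161 counts over the 16 libraries of a table. The totals per library, spike-ins included, ran from 10.8M to 20.4M counts with a median of 14.5M, and this depth and the 8 libraries per group limit the precision of each value.

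Counts of each comparison were fitted with edgeR 4.0.16 in R 4.3.3, on gene rows without the spike-ins. Genes passed filterByExpr on the compared groups, libraries were scaled by TMM, and the quasi-likelihood F-test was used with Benjamini-Hochberg adjustment and a threshold of 0.05. If p-values were spread evenly, 739 to 773 tested genes would have an unadjusted p under 0.05, depending on the comparison. Unless another tool is named, an adjusted p is from this edgeR test, and an SE is the absolute log2 change divided by the square root of F. Doxorubicin was compared with PBS within each region and genotype on 16 libraries, with sex as a covariate. The difference between the female and the male effect was tested on the same 16 libraries with a sex by treatment term. In the 32 libraries of a region, a genotype by treatment term gave the ApoE4 effect minus the ApoE3 effect, and the same fit gave ApoE4 against ApoE3 in PBS rats. In the 32 libraries of a genotype, a region by treatment term gave the hippocampal effect minus the cortical effect. Log2 CPM values carry a prior count of 1.

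Gene lists, 38 in number with 752 genes of which 653 matched a row (4 through a synonym), were written down before the data were examined, with the gene tests, the list tests for doxorubicin and for genotype, and the rule for naming genes. The list tests by sex and by region, fry for genotype and the settings named as chosen later were not among them. They cover cell types, neighbouring tissues, DNA damage, stress, immune and metabolic pathways. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes. Where a test compares effects between sexes, genotypes or regions, rose and fell refer to the difference of the effects. They do not give the direction of expression in either group. It was repeated with the correlation estimated from the data, and fry, which tests whether the members of a list move on balance in 1 direction, was run beside it. With the estimated correlation 0 lists passed in any comparison, so every camera call below rests on the preset. By fry 1 list passed by sex in ApoE3 cortex. For genotype in PBS rats, 2 passed by fry in hippocampus and 15 in cortex, and 0 in every other comparison. A list's score in a library is the mean log2 CPM of its members.

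Symbols for 15432 identifiers came from the authors' comparison tables. The genes named in each comparison are the 8 with the smallest p in each direction among those that passed with an average log2 CPM of at least 0 and an official symbol. Bare identifiers, LOC and RGD symbols and clone names were left out of this choice, and so, beyond the rule as first written, were RNA family names and mitochondrially encoded genes. Where fewer than 8 passed, all that passed are named, with the 3 of smallest p in each direction as values that did not pass. The 4 members of smallest p are named for described lists, and Apoe, Cdkn1a, Gfap, Mbp, Fos and Ttr and the donor row were always read out. Tph1 and the genes counted with it were chosen after their values were seen. Some genes that these rules name are not reported here.

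Group differences in library totals, spike-in share and marker scores were tested by exact two-sided permutation over all 12870 divisions of 8 against 8, or over the 4900 divisions within sex for a sex by treatment difference. Correlations of fold changes across genes were compared with 100 drawn regroupings of the rats. Other groupings of the same libraries were drawn 100 times for edgeR and for DESeq2, the real one included, and for DESeq2 the first 30 had been read before the others were drawn. In the ApoE4 doxorubicin comparisons, some drawn groupings gave the meningeal, myelin, mitochondrial and ribosomal lists a smaller camera p than the real grouping. A small camera p at the preset is therefore no measure of strength. The same rat numbers appear in both regions, so a pairing was checked on residuals after group and sex. The median correlation of a rat's hippocampus with its own cortex was 0.096 (from -0.106 to 0.253), it was above 0.1 in 16 of 32 rats, and the median with other rats of the group was -0.031. The region comparison was therefore also fitted with rat as a replicate block.

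Alternatives were size factors of DESeq2, no low-count filter, DESeq2 1.42.0 as the test, no sex covariate, 1 surrogate variable (sva 3.50.0), marker scores as covariates, all 32 libraries of a region in 1 fit, the 16 PBS libraries alone, and leaving out each rat in turn. The procedure was tested on simulated counts with the dispersions of each comparison and 200 changed genes. Each simulated gene was drawn independently, so differences that many genes of a library share are absent from these counts. For doxorubicin in ApoE3 hippocampus it called 162 genes, 8 of them falsely, and found 17 of 50 genes changed 1.25-fold, 39 of 50 changed 1.5-fold and 48 of 50 changed 2-fold. DESeq2 on the same simulated counts called 187 genes, 28 of them falsely. In ApoE4 hippocampus, ApoE3 cortex and ApoE4 cortex it called 170, 176 and 186, of which 15, 15 and 17 were false. The false calls of edgeR there were 4, 9 and 6.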

Results

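The data are read counts per gene in 64 RNA sequencing libraries from the hippocampus and cortex of rats with ApoE3 or ApoE4, the forms of apolipoprotein E that carry lower and higher risk of Alzheimer disease. The rats received doxorubicin or PBS, and the study asks how the drug alters the brain in each genotype. Doxorubicin was given at 2 mg/kg once a week for 4 weeks, and tissue was taken 5 to 6 weeks after the last dose. Each region, genotype and treatment had 8 libraries, 4 male and 4 female. The totals ran from 10.8M to 20.4M counts, the ERCC spike-ins took 0.932% to 2.44% of a library, and mitochondrially encoded transcripts took 6.22% to 10.6%.

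Marker genes followed the labels. The Y-linked genes Kdm5d and Eif2s3y reached 36.7 to 55.9 and 53.6 to 74.0 CPM in male libraries and at most 0.077 CPM in female ones. Prox1, a transcription factor of dentate granule cells, ran from 68.2 to 115 CPM in hippocampus and from 10.6 to 18.6 CPM in cortex. The rat Apoe row held 3.10 to 8.86 CPM in every library, whereas the ApoE3 donor row held 1200 to 3170 CPM in both genotypes.

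In the hippocampus of ApoE3 rats, doxorubicin was accompanied by lower expression of meningeal, vascular and immune gene lists and by higher expression of myelin genes. These are camera calls. Regroupings of the same libraries often gave as many passing lists, so chance was not excluded for their number. The meningeal fibroblast list fell, with 17 of 17 members lower and a mean log2 change of -1.34 (8 doxorubicin and 8 PBS libraries). The myelin list rose, with 16 of 18 members higher and a median log2 change of 0.20. Camera gave an adjusted p of 6.34e-24 for the meningeal list and 3.78e-13 for myelin, and both had adjusted p = 0.332 with an estimated correlation.

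Among the meningeal genes, the collagens Col1a1 (log2 change -2.05, SE 0.48), Col6a1 (-1.17, SE 0.25) and Col6a2 (-0.96, SE 0.19) and the transporter Slc6a20 (-2.06, SE 0.48) had the smallest p. Over all genes 0 meningeal members passed with edgeR and 14 passed when adjusted over the list alone, while the authors' DESeq2 table gives these 4 genes adjusted p from 0.00551 to 0.0148. Contractile genes of vascular smooth muscle were lower: Acta2 had a log2 change of -1.66, Tagln of -1.44 and Myh11 of -1.33. The pericyte and smooth muscle list fell with 9 of 11 members lower (adjusted p = 9.21e-07 by camera; adjusted p = 0.332 with an estimated correlation), and 5 members passed when adjusted over the list alone. The endothelial list fell with 13 of 16 members lower (adjusted p = 9.92e-06 by camera; adjusted p = 0.332 with an estimated correlation). Its members Cdh5, the cadherin of endothelial junctions (-0.89, SE 0.21), Vwf (-0.87), Esam (-0.47) and Tek (-0.36) were among 6 that passed when adjusted over the list alone.

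Complement genes fell with 12 of 13 members lower (adjusted p = 1.60e-06 by camera; adjusted p = 0.332 with an estimated correlation). C1qc had a log2 change of -0.35 and Serping1, the inhibitor of the first complement component, of -1.17, and 6 members passed when adjusted over the list alone. Antigen presentation genes fell with 12 of 12 lower, among them the class II genes RT1-Ba (-1.74), RT1-Bb (-1.84), RT1-Da (-1.73) and the invariant chain Cd74 (-1.52). Camera gave that list an adjusted p of 9.81e-06, with adjusted p = 0.448 with an estimated correlation, and 5 members passed when adjusted over the list alone. Interferon response genes fell (21 of 23 lower, adjusted p = 9.07e-05 by camera; adjusted p = 0.536 with an estimated correlation), with Gbp2 at -0.58 and Oas1a at -0.91. The reactive astrocyte list fell with 12 of 15 members lower (adjusted p = 0.000558 by camera; adjusted p = 0.448 with an estimated correlation), led by Cp (-1.42), Vim (-1.01), Fbln5 (-0.95) and Emp1 (-0.77), which fibroblasts or vessels also express. Gfap, the astrocyte filament of the same list, had a log2 change of 0.05 (SE 0.08). Senescence and inflammatory factors fell with 8 of 9 members lower (adjusted p = 0.0213 by camera; adjusted p = 0.448 with an estimated correlation). Ribosomal protein genes were lower by a median of -0.06, with 39 of 40 lower (adjusted p = 7.05e-08 by camera; adjusted p = 0.515 with an estimated correlation).

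The myelin members Opalin (0.29, SE 0.08), Ermn (0.27, SE 0.08) and Mobp (0.28, SE 0.08) were among 12 that passed when adjusted over the list alone. Excitatory synapse genes rose with 21 of 24 higher (adjusted p = 0.000640 by camera; adjusted p = 0.448 with an estimated correlation). Of these the AMPA receptor subunit Gria1 (0.16, SE 0.04) passed when adjusted over the list alone. Ependymal genes rose with 11 of 12 higher (adjusted p = 0.00104 by camera; adjusted p = 0.448 with an estimated correlation), with Ak7 at 0.73. The p53 target list, which anthracycline damage is known to induce, had 11 members higher and 11 lower and did not pass (camera adjusted p = 0.966). Its member Cdkn1a had a log2 change of 0.20 (SE 0.33).

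Among genes with an official symbol, those with the smallest p in ApoE3 hippocampus were Sec14l5 (log2 change 0.38, SE 0.07), the sodium-calcium exchanger Slc8a2 (0.20, SE 0.04), the ephrin receptor Epha7 (0.21, SE 0.04), the caveolar Cavin1 (-0.88, SE 0.17), Col6a2 and the riboflavin kinase Rfk (-0.42, SE 0.08). Each had an adjusted p of 0.170, and in each of them 8 of 8 doxorubicin libraries lay on the same side of the PBS median. With edgeR 0 of 14899 tested genes passed, 1530 had an unadjusted p under 0.05, and DESeq2 called 145 genes, 36 higher and 109 lower. The authors' table for this comparison holds 149 genes with an adjusted p under 0.05, 31 higher and 118 lower. The meningeal score of the libraries was 3.82 ± 0.58 log2 CPM (SD, n = 8) under doxorubicin and 5.04 ± 1.07 (SD, n = 8) in PBS, with an exact permutation p of 0.0145, or 0.249 adjusted over 44 tests of this kind. With that score as a covariate, chosen after the result was seen, complement, antigen presentation, interferon, reactive astrocyte, senescence and synapse lists changed sign.

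**Figure D1:**
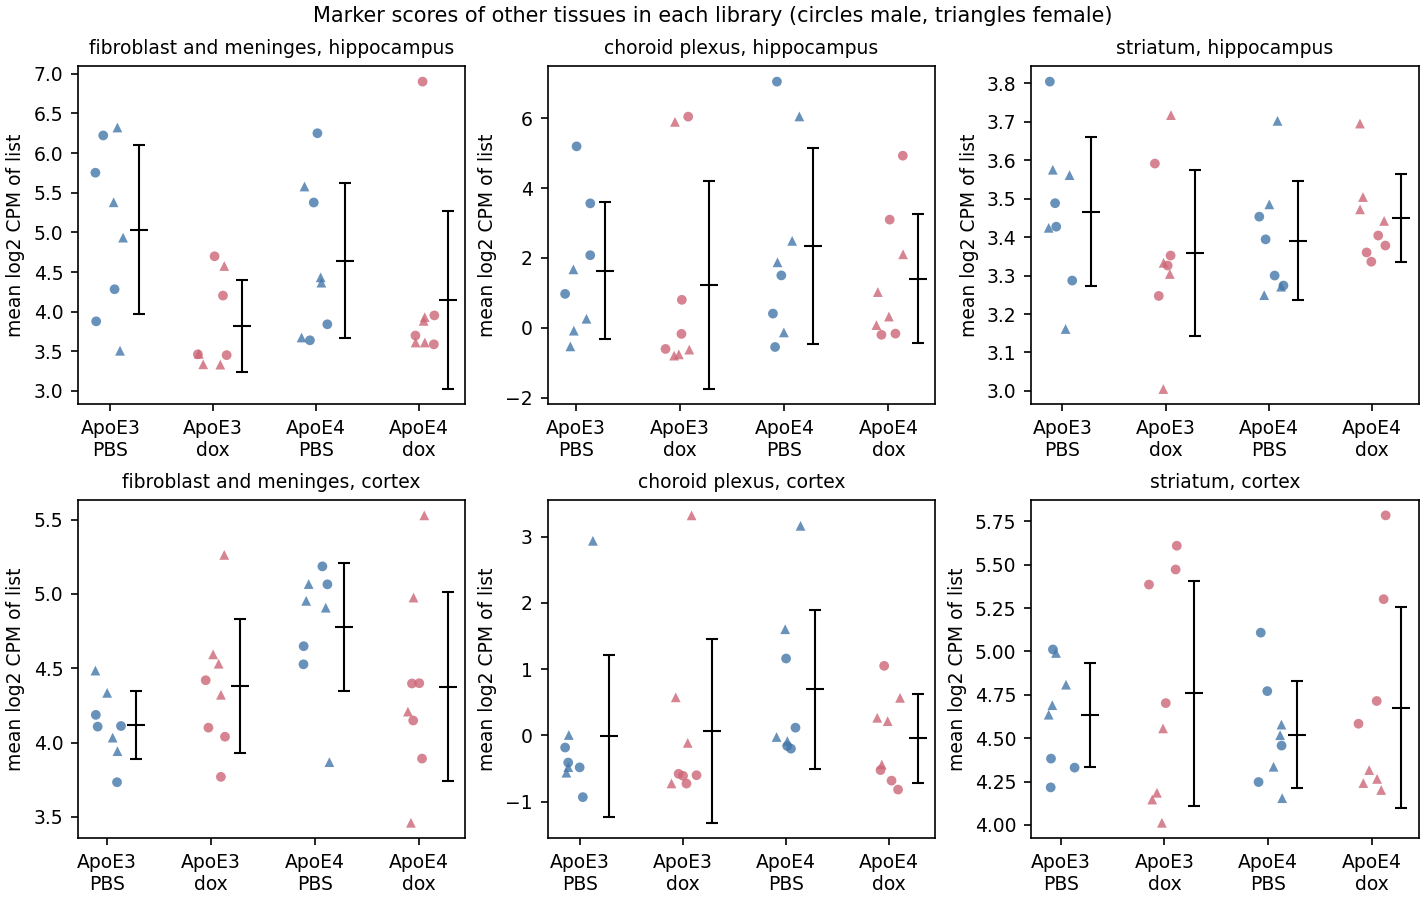
Marker scores per library, as mean log2 CPM of each list, by region, genotype and treatment (blue PBS, red doxorubicin; circles male, triangles female; bars are mean ± SD, n = 8). The meningeal score of ApoE3 hippocampus is 5.04 in PBS and 3.82 under doxorubicin, and 1 ApoE4 hippocampal library under doxorubicin stands alone at 6.90.

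In the hippocampus of ApoE4 rats, camera called inhibitory neuron genes higher under doxorubicin, and choroid plexus, ependymal, meningeal, heat shock and mitochondrially encoded genes lower. Most regroupings of the same libraries gave as many passing lists or more, so chance was not excluded for their number. The inhibitory neuron list rose with 14 of 17 members higher (adjusted p = 0.00144 by camera; adjusted p = 0.828 with an estimated correlation). It includes Gad1, which makes GABA (log2 change 0.18, SE 0.07), the peptide genes Sst (0.22, SE 0.09) and Tac1 (0.35, SE 0.15), and the vesicular transporter Slc32a1 (0.21, SE 0.10). Choroid plexus genes fell with 14 of 14 members lower and a median log2 change of -2.81 (adjusted p = 0.00194 by camera; adjusted p = 0.828 with an estimated correlation). Sostdc1 was at -3.45 (SE 1.35), Kl at -3.04 (SE 1.26), Kcnj13 at -3.00 (SE 1.19) and Ttr, the transthyretin gene that choroid epithelium makes in bulk, at -3.71 (SE 1.66). The choroid plexus score, a mean of log2 values, differed less and varied widely, at 1.40 ± 1.85 (from -0.20 to 4.93) under doxorubicin and 2.34 ± 2.81 (from -0.55 to 7.05) in PBS (SD, n = 8).

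The heat shock list fell with 16 of 19 members lower (adjusted p = 0.00779 by camera; adjusted p = 0.828 with an estimated correlation). Its members of smallest p were Hspa5 at -0.18 (SE 0.08), Manf at -0.17, Pdia6 at -0.13 and Calr at -0.11. Mitochondrially encoded transcripts fell with 12 of 13 lower and a median of -0.08 (adjusted p = 0.0108 by camera), ependymal genes with 12 of 12 lower (adjusted p = 0.0230), and meningeal genes with 15 of 17 lower (adjusted p = 0.0158). For each of these 3 lists, adjusted p = 0.828 with an estimated correlation. Over all genes and when adjusted over the list alone, 0 members of the 6 lists passed with edgeR.

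The genes with an official symbol and the smallest p were the potassium channel gene Kcnf1 (0.64, SE 0.14), Nipal3 (0.23), the kinase Camk1g (0.32), the RNA-binding Rbm45 (-0.22, SE 0.04), Tbc1d1 (-0.22) and Cep41 (-0.38), each with an adjusted p of 0.641 and 8 of 8 libraries on the same side of the PBS median. With edgeR 0 of 14873 genes passed, 1098 had an unadjusted p under 0.05, and DESeq2 called 1. The authors' table holds 1 gene, Kcnf1, with an adjusted p under 0.05. The spike-in share of these libraries was 1.20% ± 0.140 (SD, n = 8) under doxorubicin and 1.52% ± 0.398 (SD, n = 8) in PBS, with an exact permutation p of 0.0137 and 0.249 adjusted over 44 tests. Without the doxorubicin libraries of rats 10 and 31, which stand apart in a tissue score, 12 lists passed instead of 6, and the mitochondrial and ependymal calls ended (camera adjusted p of 0.135 and 0.0737).

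In the cortex of ApoE3 rats, camera called genes of oxidative phosphorylation, ribosomes, myelin and heat shock lower under doxorubicin, and meningeal and vascular genes higher. As many lists or more passed in most regroupings of the same libraries, so chance was not excluded for their number. Nuclear genes of oxidative phosphorylation fell with 35 of 37 lower and a median log2 change of -0.07 (adjusted p = 1.10e-09 by camera; adjusted p = 0.841 with an estimated correlation). The complex I genes Ndufb8 (-0.12, SE 0.04) and Ndufa9 (-0.12, SE 0.04) were among the members of smallest p. Ribosomal protein genes fell with 40 of 41 lower, among them Rps2 at -0.19 (SE 0.05; adjusted p = 2.67e-07 by camera for the list). Myelin genes fell with 17 of 18 lower and a median of -0.11 (adjusted p = 5.36e-06 by camera), with Fa2h, which makes hydroxylated myelin lipids, at -0.20 (SE 0.06). Heat shock genes fell with 17 of 19 lower (adjusted p = 0.00108), with Hsp90aa1 at -0.33 (SE 0.10). For these 3 lists, adjusted p = 0.928 with an estimated correlation.

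Meningeal genes rose with 17 of 17 higher and a mean of 0.29 (adjusted p = 6.78e-07 by camera), with Col1a1 at 0.55 (SE 0.18), Col3a1 at 0.42 and Fn1 at 0.32. Pericyte and smooth muscle genes rose with 11 of 11 higher (adjusted p = 0.00358), with the receptor Notch3 at 0.31 (SE 0.10), and endothelial genes with 14 of 16 higher (adjusted p = 0.0339), with Vwf at 0.32 (SE 0.10). For these 3 lists too, adjusted p = 0.928 with an estimated correlation. In each of the 7 lists, 0 members passed with edgeR over all genes and 0 when adjusted over the list alone. The meningeal score of the libraries was 4.38 ± 0.45 under doxorubicin and 4.12 ± 0.23 in PBS (SD, n = 8), with an exact permutation p of 0.164. Without the doxorubicin library of rat 72 and the PBS library of rat 58, which stand apart in their choroid plexus score, the pericyte and endothelial calls ended (camera adjusted p of 0.274 and 0.684).

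The genes with an official symbol and the smallest p were the adenylyl cyclase Adcy1 (0.30, SE 0.05), the kinase Abl2 (0.30, SE 0.06) and Hmbox1 (0.34, SE 0.06), each with an adjusted p of 0.0636. Among lower genes these were the autophagy gene Map1lc3a (-0.17, SE 0.04), Rab3b (-0.17, SE 0.04) and Tprg1l (-0.15, SE 0.04), with adjusted p from 0.162 to 0.181. In all 6 genes, 8 of 8 doxorubicin libraries lay on the same side of the PBS median. With edgeR 0 of 14775 genes passed, 1366 had an unadjusted p under 0.05, and DESeq2 called 77, 68 higher and 9 lower. In 1 edgeR fit of all 32 cortex libraries, 55 genes passed, and the authors' table holds 8 genes with an adjusted p under 0.05, 7 higher and 1 lower.

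In the cortex of ApoE4 rats, mitochondrially encoded transcripts were lower under doxorubicin, together with glial, vascular, meningeal and choroid plexus genes, and neuronal and clock genes were higher. The mitochondrial list fell with 13 of 13 members lower and a mean log2 change of -0.20 (adjusted p = 4.85e-17 by camera; adjusted p = 0.335 with an estimated correlation). Mt-atp6 was at -0.23 (SE 0.06), Mt-co2 at -0.23 (SE 0.06) and Mt-co3 at -0.21 (SE 0.06). Of this list 0 members passed over all genes with edgeR and 13 when adjusted over the list alone, while the authors' DESeq2 table gives Mt-atp6 and Mt-co2 an adjusted p of 0.0455. These transcripts took 7.99% of counts under doxorubicin and 9.10% in PBS, with an exact permutation p of 0.0172, or 0.249 adjusted over 44 tests.

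The clock list rose with 11 of 15 members higher (adjusted p = 0.000292 by camera; adjusted p = 0.335 with an estimated correlation). Ciart (0.53, SE 0.11), Per3 (0.32, SE 0.07) and Dbp (0.31, SE 0.08), which peak together in the daily cycle, were among 4 higher members that passed when adjusted over the list alone. Arntl, the clock activator that runs opposite to them, was at -0.20 (SE 0.06) and was the 1 lower member that passed. Inhibitory neuron genes rose with 13 of 17 higher (adjusted p = 0.00623 by camera), and Gad1 and Slc32a1, each at 0.15 (SE 0.04 and 0.05), passed when adjusted over the list alone. Excitatory synapse genes rose with 16 of 24 higher (adjusted p = 0.00967 by camera), and the receptor subunits Grin2a (0.28, SE 0.09) and Gria1 (0.15, SE 0.05) passed when adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.362 and adjusted p = 0.466. Cortical neuron, striatal and cholesterol synthesis lists rose by camera with adjusted p from 0.00896 to 0.0461, and each lost the call (adjusted p from 0.362 to 0.557 with an estimated correlation).

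Meningeal genes fell with 17 of 17 lower and a mean of -0.34 (adjusted p = 3.02e-07 by camera), led by Col6a1 at -0.60 (SE 0.14), and choroid plexus genes with 9 of 10 lower (adjusted p = 0.000314), led by Clic6 at -1.74 (SE 0.61). For the meningeal list another grouping of these libraries gave an unadjusted camera p of 1.5e-31, against 1.63e-08 for the real one. When adjusted over the list alone, 1 meningeal and 5 choroid plexus members passed. Pericyte genes fell with 11 of 11 lower (adjusted p = 0.000434) and astrocyte genes with 11 of 14 lower (adjusted p = 0.000434), where the connexin Gjb6 (-0.26, SE 0.06) passed when adjusted over the list alone. These 4 lists had adjusted p = 0.362 with an estimated correlation. Endothelial genes fell with 16 of 16 lower (adjusted p = 0.000487 by camera; adjusted p = 0.408 with an estimated correlation), myelin genes with 17 of 18 lower (adjusted p = 0.000547; adjusted p = 0.510 with an estimated correlation) and ribosomal genes with 38 of 39 lower (adjusted p = 7.59e-07; adjusted p = 0.424 with an estimated correlation). Complement genes fell with 11 of 13 lower (adjusted p = 0.00225 by camera; adjusted p = 0.362 with an estimated correlation), and C1qa (-0.19, SE 0.06) passed when adjusted over the list alone. Antigen presentation, ependymal, precursor, reactive astrocyte, microglial, interferon, heat shock and proliferation lists fell too, with camera adjusted p from 0.00147 to 0.0461 (adjusted p from 0.362 to 0.557 with an estimated correlation).

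The genes with an official symbol and the smallest p in each direction were the ceramide synthase Cers6 (0.33, SE 0.07), Clstn2 (0.25, SE 0.05), Ciart, the thiamine transporter Slc19a2 (-0.23, SE 0.05), the cyclin Ccnd1 (-0.26, SE 0.06) and Gjb6, each with an adjusted p of 0.273 and at least 7 of 8 libraries on the same side of the PBS median. With edgeR 0 of 14838 genes passed, 1308 had an unadjusted p under 0.05, and DESeq2 called 37, 28 higher and 9 lower. The authors' table holds 28 genes with an adjusted p under 0.05, 21 higher and 7 lower. Of the 24 lists, 15 passed with 1 surrogate variable and 10 with the meningeal score as a covariate, chosen after the result was seen. With that score the meningeal, vascular, immune, microglial, reactive astrocyte, proliferation, cholesterol, striatal, cortical neuron and excitatory synapse calls ended.

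**Figure D2:**
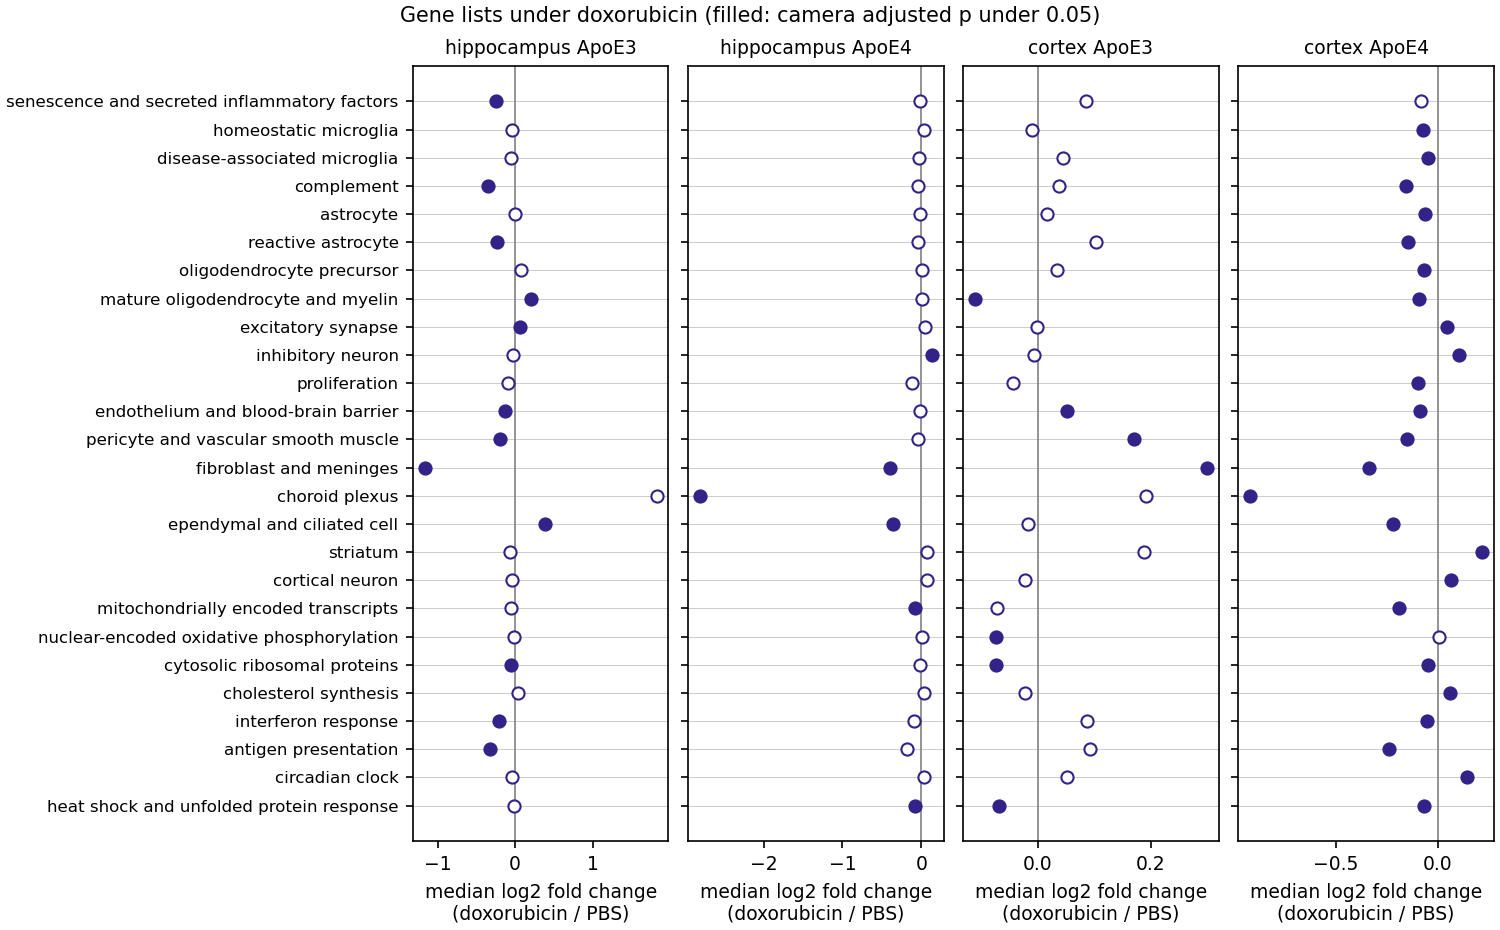
Median log2 change of the members of each gene list under doxorubicin (filled, camera adjusted p under 0.05), 1 panel per region and genotype, each panel with its own horizontal scale. The meningeal list lies at -1.17 in ApoE3 hippocampus, 0.30 in ApoE3 cortex and -0.34 in ApoE4 cortex.

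In the cortex of ApoE3 rats, the difference between doxorubicin and PBS libraries was not the same in females and males. A different drug response and different amounts of striatal tissue in the libraries were not told apart. In ApoE3 cortex 358 of 15267 genes had different effects in the sexes, 103 with a higher female than male effect and 255 with a lower one (4 libraries per sex and treatment). DESeq2 gave 763, edgeR without the low-count filter 631, and edgeR with the meningeal score as a covariate 89. Genes of striatal projection neurons led the decrease: the dopamine receptor Drd2 had a female minus male log2 difference of -2.27 (SE 0.39, adjusted p = 0.00348), and Scn4b of -1.49 (SE 0.15, adjusted p = 1.22e-05). Scn4b was higher under doxorubicin in males by a mean log2 difference of 0.90 and lower in females (-0.58), and 4 of 4 libraries of each sex lay on that side of their PBS median.

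Of 37 lists, tested by sex only after the data had been seen, 14 rose and 5 fell by camera, while 0 passed with an estimated correlation and 1 by fry. The striatal list fell with 14 of 14 members lower (adjusted p = 3.67e-26 by camera; adjusted p = 0.0851 with an estimated correlation), and fry gave it an adjusted p of 0.0171. Over all genes 12 of its members passed, among them Ppp1r1b, the dopamine signalling protein DARPP-32 (-0.99, SE 0.18), and the phosphodiesterase Pde10a (-1.09, SE 0.20), and 14 passed when adjusted over the list alone. The striatal score was 4.49 log2 CPM in male PBS and 5.29 in male doxorubicin libraries, against 4.78 and 4.23 in females, and the sex by treatment difference was -1.36 with an exact permutation p of 0.00204. Inhibitory neuron genes fell with 11 of 17 lower (adjusted p = 0.00132 by camera; adjusted p = 0.415 with an estimated correlation). The GABA enzymes Gad2 (-0.56, SE 0.09) and Gad1 (-0.52, SE 0.13), the transporter Slc32a1 (-0.43) and the peptide Vip (-0.54) were among 5 members that passed over all genes, and 6 passed when adjusted over the list alone. Cortical neuron genes fell with 13 of 18 lower (adjusted p = 2.30e-05 by camera; adjusted p = 0.415 with an estimated correlation), where Bcl11b (-0.56, SE 0.15) passed over all genes with Scn4b, which 2 lists hold, and 8 members passed when adjusted over the list alone. The NMDA receptor subunit Grin2a stood at -1.02 (SE 0.16, adjusted p = 0.00165).

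Other genes with a lower effect in females were the synaptic pentraxin Nptx2 (-0.99, SE 0.11), Arpp19 (-0.69), the potassium channel Kcnh7 (-1.10), the calcium-dependent kinase Camk4 (-0.89), Cdh12 (-0.86), Dgkb (-0.72) and Pcp4 (-0.83), with adjusted p from 6.43e-05 to 0.00119. Genes with a higher effect in females were Tshz2 (1.27, SE 0.21), Lmo4 (0.51, SE 0.08), Tbkbp1 (0.51), Mpnd (0.56), Nat8f3 (0.93), Oplah (0.49) and Carmil3 (0.66), with adjusted p from 0.00285 to 0.00908. In each of these 14 genes, 4 of 4 female and 4 of 4 male doxorubicin libraries lay on opposite sides of their own PBS medians. Pericyte genes rose with 10 of 12 higher (adjusted p = 2.42e-05 by camera; adjusted p = 0.415 with an estimated correlation). Notch3 (0.62, SE 0.16) and Pdgfrb (0.49, SE 0.13) passed over all genes, and 8 passed when adjusted over the list alone. The clock gene Per2 had a difference of 0.97 (SE 0.21, adjusted p = 0.0167), and the ApoE3 donor row of 0.51 (SE 0.13, adjusted p = 0.0340).

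Leaving out single libraries moved this count from 104 to 686, and without the doxorubicin library of rat 72 and the PBS library of rat 58, which stand apart in their choroid plexus score, 91 genes passed. With the striatal score as a covariate, chosen after the result was seen, 17 genes passed. In ApoE4 cortex 1 gene passed, Dact2 (0.57, SE 0.09, adjusted p = 0.0488), with 896 at an unadjusted p under 0.05 and 21 by DESeq2. With edgeR 0 genes passed there in 13 of 16 fits that each leave out 1 library and with the striatal score as a covariate, and 11 of 100 regroupings gave as many as the real one. The striatal score of ApoE4 cortex had a sex by treatment difference of -0.59 (exact permutation p = 0.112). In the hippocampus 0 of 15462 genes passed with edgeR in ApoE3 (696 at an unadjusted p under 0.05, 0 by DESeq2). In ApoE4 hippocampus 0 of 15390 passed (543 at an unadjusted p under 0.05, 1 by DESeq2). Both counts at an unadjusted p under 0.05 lay below the 773 and 770 that evenly spread p-values would give.

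Whether the genotypes respond differently to doxorubicin was tested directly. Regroupings of the libraries did not exclude chance for the number of lists that passed by camera in either region. In the hippocampus, meningeal genes had a higher effect in ApoE4 than in ApoE3 rats, and choroid plexus, ependymal and myelin genes a lower one. For the meningeal list the difference of effects was higher in 15 of 17 members (adjusted p = 0.000103 by camera), although its score was lower under doxorubicin in both genotypes. Lum, a matrix proteoglycan, was at 1.41 (SE 0.46) and Col6a2 at 1.04 (SE 0.35), and these 2 members passed when adjusted over the list alone. Myelin genes fell with 16 of 18 lower (adjusted p = 0.000103), with Ugt8 at -0.29 (SE 0.13), and ependymal genes with 11 of 12 lower (adjusted p = 0.000103), with Tekt1 at -1.24. Choroid plexus genes fell with 15 of 16 lower (adjusted p = 0.00807), with Prlr at -5.73 (SE 1.83), and 14 passed when adjusted over the list alone. Their score in ApoE3 rats was 1.22 ± 2.98 (from -0.80 to 6.04) under doxorubicin and 1.64 ± 1.95 (from -0.53 to 5.19) in PBS (SD, n = 8), so libraries within a group differed by more than the groups did. Inhibitory neuron, pericyte, ribosomal and cortical neuron lists rose and the hippocampal neuron list fell, with camera adjusted p from 0.00340 to 0.0458, and for all 9 lists adjusted p = 0.866 with an estimated correlation. Without the doxorubicin libraries of ApoE4 rats 10 and 31, the meningeal call ended (camera adjusted p of 0.135).

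In the cortex, meningeal genes had a lower effect in ApoE4 rats with 17 of 17 lower (adjusted p = 4.10e-13 by camera), among them Col6a1 (-0.71, SE 0.19) and Fmod (-1.04, SE 0.36), which passed when adjusted over the list alone. Pericyte genes fell with 12 of 12 lower (adjusted p = 1.20e-06), with Notch3 at -0.45 and Anpep at -0.65, and endothelial genes with 16 of 16 lower (adjusted p = 2.12e-05), with Vwf at -0.52. Oxidative phosphorylation genes rose with 34 of 37 higher (adjusted p = 1.20e-06), with Ndufb8 at 0.16 (SE 0.05). Mitochondrially encoded transcripts fell with 13 of 13 lower (adjusted p = 0.000773). Of the other 10 lists that passed, 3 rose and 7 fell, and for all 15 lists adjusted p = 0.542 with an estimated correlation.

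Over all genes 0 passed this test with edgeR in the hippocampus (1261 at an unadjusted p under 0.05, 2 by DESeq2) and 0 in the cortex (834 at an unadjusted p under 0.05, 0 by DESeq2). Evenly spread p-values would give 771 and 766 at that level. Across genes, which are not independent replicates, the doxorubicin effects of the genotypes had a Pearson r of -0.247 in hippocampus (permutation p = 0.57, Spearman rho 0.012, permutation p = 0.94) and of 0.049 in cortex (permutation p = 0.63, rho 0.117, permutation p = 0.34). Adjusted over the 4 such relations, r had p of 0.63 in both.

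**Figure D3:**
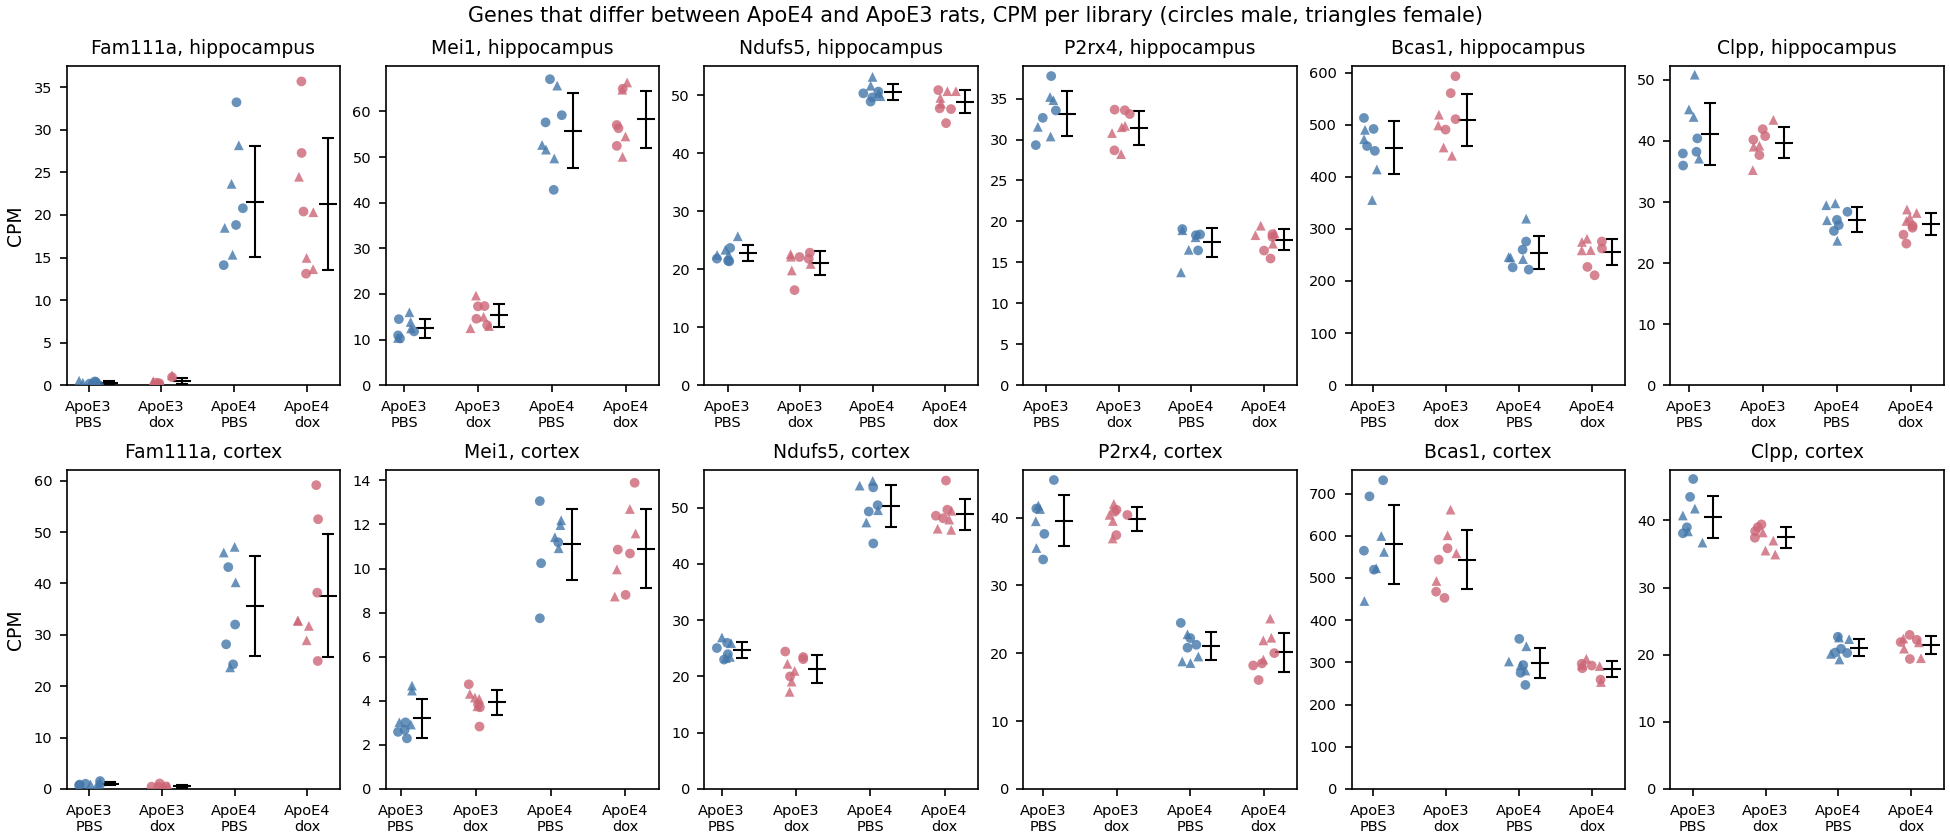
CPM per library of 6 genes that differed between ApoE4 and ApoE3 rats, by region, genotype and treatment (blue PBS, red doxorubicin; circles male, triangles female; bars are mean ± SD, n = 8). In each panel the 8 PBS libraries of ApoE4 lie apart from the 8 PBS libraries of ApoE3.

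ApoE4 and ApoE3 rats given PBS differed in many genes, and some of the differences with the smallest p were shared by the 2 regions. Ndufs5, a subunit of respiratory complex I, stood at 50.6 ± 1.32 CPM in ApoE4 and 22.8 ± 1.44 CPM in ApoE3 hippocampus (SD, n = 8), and at 50.3 ± 3.75 and 24.7 ± 1.47 CPM in cortex. Fam111a, a protease gene of antiviral defence, stood at 21.6 ± 6.51 CPM in ApoE4 and 0.273 ± 0.170 CPM in ApoE3 hippocampus, and at 35.6 ± 9.70 and 1.04 ± 0.281 CPM in cortex. P2rx4, an ATP-gated channel found on microglia, was lower in ApoE4, at 17.4 ± 1.78 against 33.1 ± 2.76 CPM in hippocampus and 21.1 ± 2.07 against 39.5 ± 3.77 CPM in cortex. In hippocampus 588 of 15416 genes passed, 297 higher and 291 lower in ApoE4, and in cortex 2788 of 15315 passed, 1475 higher and 1313 lower. Of 15023 genes tested in both, 376 passed in both, 375 of them with the same sign, where 105 would pass in both if the calls were independent.

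Genes higher in ApoE4 in both regions included Mei1 (log2 difference 2.16, SE 0.11 in hippocampus; 1.79, SE 0.13 in cortex), the zinc finger genes Zfp61 (0.72 and 0.62) and Zfp180 (0.50 and 0.59), with adjusted p of at most 1.83e-09. Zfp61 and Zfp180 lie 20 and 12 genes from Apoe, the gene replaced in these rats. In hippocampus Hdhd2 (0.50), the ubiquitin ligase adaptor Klhl22 (0.99) and the mitochondrial Rtn4ip1 (0.76) also led, and in cortex the interferon lambda receptor Ifnlr1 (2.83), the protocadherin Pcdhb6 (2.37) and the pyrimidine-degrading Dpyd (1.23). Genes lower in both were Bcas1, a marker of newly formed oligodendrocytes (-0.84, SE 0.08 and -0.96, SE 0.08), the mitochondrial protease Clpp (-0.60 and -0.95), Ube2v1 (-0.60 and -0.60), Ghdc (-1.84 and -1.69) and Pcdhb8 (-1.52 and -1.53). The lysosomal sulfatase Arsb (-0.40) and the sulfotransferase Chst8 (-0.90) were lower in hippocampus, and Igfbp6 (-2.02) and the synaptotagmin Syt5 (-0.54) in cortex. For every gene in these sentences, 8 of 8 PBS libraries of ApoE4 lay beyond all 8 of ApoE3. The ApoE3 donor row was lower in ApoE4 rats, by a log2 difference of -0.34 (SE 0.07, adjusted p = 0.00251) in hippocampus and -0.23 (SE 0.08, adjusted p = 0.0400) in cortex, where it no longer passed in the 16 PBS libraries alone (-0.22, adjusted p = 0.0622). The sequence behind this row is not given in the sources used here, and whether expression was lower or ApoE4 reads matched it less well was not tested.

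Mitochondrially encoded transcripts were higher in ApoE4, with 13 of 13 higher in hippocampus (adjusted p = 1.04e-12 by camera; adjusted p = 0.394 with an estimated correlation) and 13 of 13 in cortex (adjusted p = 0.000141; adjusted p = 0.522 with an estimated correlation). Mt-cyb was higher by 0.27 (SE 0.05) and 0.33 (SE 0.08), and 6 members passed over all genes in each region, with 13 and 10 when adjusted over the list alone. In hippocampus myelin genes rose with 17 of 18 higher (adjusted p = 2.63e-06 by camera; adjusted p = 0.810 with an estimated correlation). Mbp (0.32, SE 0.08), Ermn (0.33) and Fa2h (0.28) passed over all genes, and 8 members passed when adjusted over the list alone. Clock genes fell there with 11 of 15 lower (adjusted p = 0.00914 by camera; adjusted p = 0.394 with an estimated correlation). Ciart (-0.51, SE 0.10) and Dbp (-0.48, SE 0.10) passed over all genes, and 4 lower members and 1 higher passed when adjusted over the list alone. Ependymal genes rose with 11 of 12 higher (adjusted p = 0.0202; adjusted p = 0.810 with an estimated correlation), with 0 members passing. For the number of lists passing by camera, regroupings did not exclude chance in hippocampus or in cortex.

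In cortex ribosomal protein genes were lower in ApoE4, with 39 of 41 lower (adjusted p = 4.29e-08 by camera). Rpl27 was at -0.23 and Rps2 at -0.33, while Rps16 was at 0.46 (SE 0.05). Over all genes 24 ribosomal members fell and 2 rose, and 28 and 2 passed when adjusted over the list alone. Oxidative phosphorylation genes fell with 34 of 37 lower (adjusted p = 7.09e-05), with Ndufb8 at -0.27 (SE 0.04), and 12 members passed over all genes and 12 when adjusted over the list alone. Meningeal genes rose with 16 of 17 higher (adjusted p = 3.63e-06), with Col3a1 at 1.28 (SE 0.27), Col1a1 at 1.23 and Lum at 1.05, and 11 passed over all genes and 13 when adjusted over the list alone. Endothelial genes rose with 14 of 16 higher (adjusted p = 0.000165), with Kdr at 0.52 and Tek at 0.48, and 7 passed over all genes and 9 when adjusted over the list alone. Interferon genes rose with 21 of 24 higher (adjusted p = 0.00110), with Mx2 at 1.46 (SE 0.16), and 7 passed over all genes and 7 when adjusted over the list alone. Astrocyte genes rose with 11 of 14 higher (adjusted p = 0.00419), where the glutamate transporter Slc1a2 was at 0.61 (SE 0.08), and 5 passed over all genes and 5 when adjusted over the list alone. Genes of lipid transport rose with 15 of 20 higher (adjusted p = 0.0136), and the receptor Lrp1 (0.31, SE 0.05) and the cholesterol exporter Abca1 (0.37, SE 0.07) were among 4 that rose over all genes and 5 when adjusted over the list alone, beside 1 that fell. For these 7 lists, adjusted p = 0.522 with an estimated correlation. By fry, chosen after the data were seen, 2 lists passed in hippocampus and 15 in cortex. Antigen presentation, extracellular matrix, reactive astrocyte, pericyte, precursor and myelin lists rose by camera as well, with adjusted p from 0.00567 to 0.0448 (adjusted p from 0.522 to 0.809 with an estimated correlation).

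Whether the drug acted differently on the regions was tested in the 32 libraries of each genotype, for gene lists only after the data had been seen. In ApoE3 rats camera called the effect in hippocampus lower than in cortex for meningeal and pericyte genes and higher for myelin genes. Of 38 lists, 5 rose and 9 fell by camera, and 0 passed with an estimated correlation or by fry. The meningeal list fell with 17 of 17 lower and a mean difference of -1.64 (adjusted p = 2.34e-28 by camera; adjusted p = 0.0878 with an estimated correlation), and 15 members passed when adjusted over the list alone. The myelin list rose with 17 of 18 higher (adjusted p = 1.17e-18 by camera; adjusted p = 0.108 with an estimated correlation), and 13 passed when adjusted over the list alone. Pericyte genes fell with 12 of 12 lower (adjusted p = 3.60e-11 by camera; adjusted p = 0.108 with an estimated correlation), and 8 passed when adjusted over the list alone.

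With edgeR 0 genes passed in ApoE3 (1235 at an unadjusted p under 0.05, 126 by DESeq2) and 0 in ApoE4 (554 at an unadjusted p under 0.05, 0 by DESeq2). Evenly spread p-values would give 771 and 772 at that level. With rat as a replicate block 9 passed in ApoE3 and 0 in ApoE4. Genes with a higher effect in hippocampus included the myelin genes Fa2h (0.41), Opalin (0.34) and Ugt8 (0.41). The 5 with a lower effect were Col6a2 (-1.03), Col12a1 (-0.96), the adipsin gene Cfd (-2.41), Fgl2 (-1.13) and Tph1 (-11.31), which reached 1630 CPM in 1 hippocampal PBS library. Across genes, the effects in the 2 regions of ApoE4 rats had a Pearson r of 0.316 (permutation p = 0.05, 0.2 adjusted over the 4 relations) and a Spearman rho of 0.265 (permutation p = 0.02, 0.08 adjusted). In ApoE3 rats r was -0.105 (permutation p = 0.44) and rho 0.055 (permutation p = 0.73). In ApoE4 rats myelin, mitochondrially encoded and ribosomal lists had a higher effect in hippocampus, with camera adjusted p from 0.000121 to 0.00179 (adjusted p = 0.961 with an estimated correlation).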

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

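The tests of correlated meningeal genes, of the meningeal score by region and of equal library sizes, the fits with meningeal, striatal and 3 tissue scores, fry for genotype by doxorubicin, the Apoe windows of 25, 50 and 200, and the DESeq2 groupings beyond the first 30 were chosen after the results were seen, and how to read the 2 library size tests and the Apoe neighbour test was changed once their p-values were known, since a p above 0.05 excludes nothing. Of 120 groups of libraries examined, 25 had a library far from the rest, and chance gives this in about 1 in 20 groups of normally distributed values, a rate not computed here for skewed CPM values.

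The meningeal list fell under doxorubicin in ApoE3 hippocampus by camera (adjusted p = 0.332 with an estimated correlation). The values argue against a change of like size in both regions: the meningeal score differed by -1.22 (95% interval -2.17 to -0.27) in hippocampus and by 0.26 (95% interval -0.13 to 0.66) in cortex. The planned test correlated the score within groups between both regions of 16 rats (r = -0.145, upper 95% limit 0.378, permutation p = 0.596). This met the bound set against a change carried by the rat. However, such deviations from group means hold no drug effect, so that test cannot decide it. Different amounts of meningeal tissue in the libraries may lie behind the decrease, since pairs of meningeal genes correlated within groups at a median of 0.848, although a loss of meningeal cells in the animal would look the same. A difference in library size is argued against too: total counts gave an exact permutation p of 0.938, and the 95% interval of their log2 ratio, -0.19 to 0.20, stays far from the mean log2 change of -1.34. The 1530 genes at an unadjusted p under 0.05 met the bound set beforehand, a share of groupings under 0.05. The highest other grouping gave 1638, and 3 of 100, the real one included, gave as many. The 145 of DESeq2 met it too (highest other 178, 2 of 100). With 26 such tests and no correction, these shares do not exclude chance. The 12 lists did not meet the bound (highest other 22, 39 of 100).

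In ApoE3 cortex the difference between doxorubicin and PBS libraries was unlike in the sexes for 358 genes. The highest other grouping gave 30, and 1 of 100, the real one included, gave as many. That is the smallest share 100 groupings can give, and with 26 such tests and no correction it does not exclude chance. In the same test, a regrouping called 389 genes in ApoE4 hippocampus, and another called 176 in ApoE3 hippocampus. Striatal tissue in part of the cortex libraries is a candidate explanation that stays open. Of 346 passing genes outside the striatal list, 70.8% had the sign that their slope on the striatal score in ApoE4 cortex gives. This lies between the 75% and 55% set beforehand, against 51.2% of other genes. Over the 346 genes, slope and sex difference correlated at -0.546, the direction that the sex by treatment difference of the striatal score gives. The mean striatal score ran from 4.15 to 5.78 in those ApoE4 libraries, and the cortex itself expresses Scn4b, Foxp1 and other members. A difference in library size is argued against for these 358 genes (exact permutation p = 0.717 for total counts). With all libraries thinned at random to equal totals, 321 to 420 genes passed in 20 draws. In every draw at least 99.4% of the 358 kept their sign, and their log2 differences correlated with the unthinned ones at 0.994 or more. A median of 80.8% passed with the same sign, but the lowest draw, 76.0%, missed the 80% set before the draws. A response that differs between females and males stays open as well and was not tested apart from tissue.

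In PBS rats 588 genes in hippocampus and 2788 in cortex differed between ApoE4 and ApoE3. No other grouping came near these counts (highest 1 and 2). In each region 1 of 100, the real one included, gave as many, the smallest share that 100 groupings can give. Different amounts of tissue types do not account for most genes shared by the regions, since 81.6% of the 375 with the same sign passed in both with choroid plexus, meningeal and striatal scores as covariates; of the 2412 that passed in cortex alone 56.2% did, which leaves that part open. Of 107 tested genes among the 100 on each side of Apoe, 6 passed in both regions, with an odds ratio of 2.32 (95% interval 0.828 to 5.29, Fisher exact p = 0.0529), so DNA around the replaced gene that differs between the lines may add to the pattern, yet 368 of the 374 named shared genes lie elsewhere. The 6 include Apoc1, next to Apoe, and Zfp180 and Zfp61, which were among the genes of smallest p in both regions. Windows added after this result was seen gave exact p of 0.00379 for 25 neighbours, 0.0439 for 50 and 0.00105 for 200. An effect of ApoE4 itself and other differences between the lines were not tested. A batch that follows genotype, which the labels do not give, could not be told apart from genotype.

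In 1 gene of ApoE4 cortex, Dact2, the response differed between the sexes by the test of that difference, but chance was not excluded, and 0 genes passed in 13 of 16 fits that each leave out 1 library and with the striatal score as a covariate (edgeR; 896 genes at an unadjusted p under 0.05 and 21 by DESeq2 with all 16 libraries). The response of 9 lists in hippocampus and 15 in cortex differed between genotypes by camera, and each lost the call (adjusted p = 0.866 and adjusted p = 0.542 with an estimated correlation, and 0 lists by fry in either region).

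Several libraries stood far from the rest of their group in tissue markers. Ttr, made in the choroid plexus, reached 2910 CPM in the ApoE3 PBS hippocampus of rat 37 (others up to 626) and 1990 CPM in the ApoE4 doxorubicin hippocampus of rat 10. In cortex it reached 755 CPM in ApoE3 PBS rat 58, 554 CPM in ApoE3 doxorubicin rat 72, 584 CPM in ApoE4 PBS rat 19 and 68.9 CPM in ApoE4 doxorubicin rat 10. The choroid plexus score was 2.94 in ApoE3 PBS rat 58 and 3.32 in ApoE3 doxorubicin rat 72. In ApoE4 doxorubicin hippocampus, rat 10 had a meningeal score of 6.90 (others 3.59 to 3.95) and 27.2 CPM of Fos, and rat 31 a striatal score of 3.70.

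Tph1, an enzyme of serotonin synthesis, reached 1630 CPM in the ApoE3 PBS hippocampus of rat 45 and 1390 CPM in the ApoE4 doxorubicin hippocampus of rat 31. It was at 144 CPM in the ApoE3 doxorubicin cortex of rat 72 and 84.8 CPM in the ApoE4 doxorubicin cortex of rat 29. Smaller departures were 4.99 CPM in ApoE3 doxorubicin hippocampus (rat 72), 6.49 CPM in ApoE4 PBS hippocampus (rat 1) and 5.52 CPM in ApoE4 PBS cortex (rat 1).

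The p53 target Cdkn1a stood at 39.9 CPM in the ApoE4 PBS hippocampus of rat 7 and at 16.1 CPM in the ApoE3 PBS cortex of rat 56. Fos was low, at 8.77 CPM, in the ApoE3 PBS cortex of rat 58. The ApoE3 donor row was at 1660 CPM in the ApoE4 doxorubicin cortex of rat 31. The spike-in share was 1.89% in the ApoE3 doxorubicin hippocampus of rat 49 and 2.44% in the ApoE4 PBS hippocampus of rat 22, and the ApoE3 doxorubicin cortex of rat 52 held 20.4M counts. The spike-ins, left out of the gene tests, took a median of 1.35% over the 64 libraries.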

How the results depend on the processing

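Fits with the meningeal, striatal or 3 tissue scores, the likelihood ratio, voom, robust and legacy edgeR tests, fry for genotype, and fits without the libraries that stand apart were chosen after seeing the data, as were all tests of lists by sex and by region; the rest were planned. Among values of named genes under the alternatives, 925 kept direction and side of the threshold, 65 passed that had not, 1 (the donor row in cortex with the 16 PBS libraries alone) no longer passed, and 9 that had not passed changed sign. Among gene lists 1317 kept direction and side, 263 no longer passed, 35 passed that had not, and 73 that had not passed changed sign. Robust and legacy edgeR gave 0 genes for doxorubicin in each table. For doxorubicin, 0 genes passed in each comparison, and DESeq2 gave 145 and 1 in hippocampus (ApoE3, ApoE4) and 77 and 37 in cortex. On simulated counts, DESeq2 called more genes than edgeR in each of these comparisons, and more of its calls were false. The simulated genes were drawn independently, so these rates need not hold for the real libraries. The likelihood ratio test gave 118, 38 and 6 in ApoE3 hippocampus, ApoE3 cortex and ApoE4 cortex, and voom 0 in each. In ApoE3 hippocampus, 1 surrogate variable gave 50 and the choroid plexus score 1. Without the low-count filter 7 (ApoE3) and 4 (ApoE4) passed in cortex, with all 32 libraries 55 and 1, with the meningeal score 5 in ApoE3 and with the choroid plexus score 14 in ApoE4. The cause was not tested.

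For list counts, the estimated correlation and fry each left 0 for doxorubicin in each of the 4 tables and for genotype by doxorubicin in both regions; for genotype in PBS rats the estimated correlation left 0 and 0, and fry 2 in hippocampus. Of the doxorubicin lists in ApoE4 cortex, 15 passed with 1 surrogate variable and 10 with the meningeal score, and 12 passed in ApoE4 hippocampus without rats 10 and 31. For sex by doxorubicin, DESeq2 gave 1 in ApoE4 hippocampus, and 763 (ApoE3) and 21 (ApoE4) in cortex, and no filter gave 631 and 16. The striatal score gave 17 and 0, of which 15 were among the 358, the meningeal score 89 and 2, and omitting rats 58 and 72 gave 91 in ApoE3. Genotype by doxorubicin in hippocampus gave 2 with DESeq2. For region by doxorubicin in ApoE3, no filter gave 40, DESeq2 126 and the rat block 9; in ApoE4 the block gave 0. The correlation of effects between regions in ApoE4 was 0.41 (permutation p = 0.04) among genes with a log2 CPM of at least 3. The cause was not tested.

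With the meningeal score as a covariate, these lists changed direction in ApoE3 hippocampus (camera adjusted p after the change): senescence 0.154, disease-associated microglia 0.0183, complement 0.969, reactive astrocyte 0.167, excitatory synapse 0.897, thalamus 0.00547, interferon 0.0129 and antigen presentation 0.0397. So did meninges in ApoE4 hippocampus (0.431), meninges (0.918) and choroid plexus (0.0210) in ApoE3 cortex, and meninges (0.835) and interferon (0.979) in ApoE4 cortex. With the choroid plexus score the choroid plexus list turned in ApoE4 cortex (0.732). A score taken from a list removes that list's own signal, so its reversal carries no weight; for the others the cause was not tested.

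Leaving out 1 library at a time, counts for doxorubicin ran from 0 to 0 in both hippocampal tables, from 0 to 2 in ApoE3 cortex (2 without PBS rat 45, 1 without PBS rat 59 or doxorubicin rat 72) and from 0 to 1 in ApoE4 cortex (1 without doxorubicin rat 10 or 31). For sex by doxorubicin they ran from 0 to 0 in both hippocampal tables and from 104 to 686 in ApoE3 cortex: 104, 119, 133 and 179 without doxorubicin rats 65, 47, 49 and 72, and 135, 144, 203 and 686 without PBS rats 58, 61, 37 and 56. In ApoE4 cortex they ran from 0 to 3, with 3 without doxorubicin rat 18, 1 without PBS rat 19 or doxorubicin rat 13, and 0 without any other.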

Other observations

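The list tests by sex, and the reading of genes that rise with Tph1, were chosen after the results were seen; the regroupings of libraries were set earlier, of which those of DESeq2 were extended from 30 to 100 after the first 30 were seen. Beyond ApoE3 cortex, camera at the preset called chaperone and cholesterol genes different in their response to doxorubicin between the sexes of ApoE4 rats. These list calls by sex were not compared with regroupings of the libraries. The heat shock list had a lower effect in females in hippocampus (17 of 19 members lower, camera adjusted p = 1.26e-08) and in cortex (16 of 19 lower, camera adjusted p = 5.67e-08). With an estimated correlation these had adjusted p = 0.125 and adjusted p = 0.227. In cortex the chaperone Hspa5 had a female minus male log2 difference of -0.41 (SE 0.09), and 6 members passed when adjusted over the list alone, against 1 in hippocampus. The cholesterol synthesis list had a higher effect in females, with 18 of 22 members higher in hippocampus (camera adjusted p = 1.03e-05; adjusted p = 0.208 with an estimated correlation) and 18 of 22 in cortex (camera adjusted p = 5.32e-09; adjusted p = 0.227 with an estimated correlation). Insig1, a sensor of the sterol pathway, was at 0.53 (SE 0.10) in cortex, and 5 members there and 2 in hippocampus passed when adjusted over the list alone.

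Immediate early genes of neuronal activity had a lower effect in females in ApoE4 cortex with 22 of 22 members lower (camera adjusted p = 1.15e-06; adjusted p = 0.947 with an estimated correlation), and a higher one in ApoE3 hippocampus with 17 of 22 higher (camera adjusted p = 0.00265; adjusted p = 0.683 with an estimated correlation). Myelin genes had a lower effect in females in ApoE3 hippocampus with 18 of 18 lower (camera adjusted p = 9.16e-07; adjusted p = 0.683 with an estimated correlation). In ApoE3 hippocampus 10 lists passed by sex with camera, in ApoE4 hippocampus 8 and in ApoE4 cortex 9. In each of these comparisons 0 passed with an estimated correlation and 0 by fry.

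The hippocampal libraries of rats 31 and 45, high in Tph1, were also high in a small group of other genes. Alox15 reached 121 and 116 CPM in rats 31 and 45, Gnat2, the cone transducin, 136 and 132 CPM, Impg2 42.4 and 54.1 CPM, and Cacna1f, a retinal calcium channel, 69.9 and 61.5 CPM. The medians of these 4 genes over the 32 hippocampal libraries lay between 0.447 and 0.735 CPM.

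Regroupings of the same libraries tested the other counts, 26 in all without correction for their number. Of these, 7 had a share of groupings under 0.05, the bound set beforehand. Each bracket gives the highest other grouping and how many groupings, the real one included, gave as much. For doxorubicin in ApoE4 cortex the 24 lists met that bound (27, 4 of 100). The 1308 genes at an unadjusted p under 0.05 (1711, 8 of 100) and the 37 of DESeq2 (94, 5 of 100) did not. With 26 tests and no correction, 3 or 4 of 100 do not exclude chance. In ApoE4 hippocampus it could not be excluded for 1098 such genes (2753, 23 of 100), 1 gene of DESeq2 (333, 36 of 100) or 6 lists (21, 83 of 100). In ApoE3 cortex the same held for 1366 genes (2446, 12 of 100) and 7 lists (23, 83 of 100). The 77 of DESeq2 met the bound (357, 3 of 100). For sex by doxorubicin chance could not be excluded in ApoE3 hippocampus (696 genes: 1935, 49 of 100), ApoE4 hippocampus (543: 3249, 64 of 100) or ApoE4 cortex (1 passing: 12, 11 of 100). For genotype by doxorubicin it could not be excluded in hippocampus (1261 genes: 2132, 17 of 100, and 9 lists: 20, 57 of 100) or in cortex (834 genes: 2068, 29 of 100, and 15 lists: 23, 19 of 100). For genotype in PBS rats it could not be excluded for the 4 lists of hippocampus (20, 91 of 100) or the 14 of cortex (21, 15 of 100), and for region by doxorubicin neither in ApoE3 (1235: 2266, 9 of 100) nor in ApoE4 (554: 2797, 63 of 100). Groupings that called several times the real number may point to a structure among the libraries other than treatment, which was not tested.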
